A study of Schmidtea mediterranea with 96 samples.

How the data were processed

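The libraries were made from polyA RNA of worms starved for at least 7 days, per the labels' protocols, which also state that an asexual and a sexual strain were kept without saying which library came from which. X1, X2 and Xins cells were sorted live on a DNA dye, and PIWI-1 populations were sorted from fixed cells. The authors deposited 3 tables with 36035 transcripts each and 1 column per library, 96 in all. The values are FPKM (reads per kilobase of transcript and per M reads of the library) as deposited by the authors, per the submitters' description of the files. Bowtie2 2.2.9 and edgeR are named in the submitters' processing notes, without a role, and neither the reference build nor the counting method is stated. The identifiers are transcripts, and no table pairing them with gene names came with the files, so gene lists written by name before the data were examined could not be used and reads shared between near-identical transcripts could not be assessed.

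Depth was recovered from the deposited FPKM values, whose low values are whole multiples of a step. One integer length per transcript and one integer total per library turned 99.99976% to 100% of values with a length into whole reads, within 0.05 of a read or the precision of the printed value, and these transcripts carried 98.3% to 98.6% of the values above 0 in the 3 tables. Between 50.4% and 54.0% of the recovered reads were odd numbers in each library, which a total found 2 times too large would not give. On simulated data, without the steps that compare the 3 tables, the recovery gave a length to 2795 of 3000 transcripts, and 99.9% of those lengths were right. It found 3 of 12 totals 2 times too large, which is why the odd numbers were checked. Recovered reads served for depth, thinning and 1 alternative test, and all other results use the deposited FPKM. One read on a transcript of 1 kb equals 0.105 FPKM in the smallest library and 0.0226 in the largest.

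Differences were tested with limma 3.58.1 (lmFit and eBayes with a mean-variance trend, two-sided moderated test, Benjamini-Hochberg adjustment) in R 4.3.3 on log2(FPKM + 1), as chosen before the data were examined. Log2 differences in the text are on that scale, so they understate ratios for transcripts near 0. A transcript entered a fit with at least 1 FPKM in 3 libraries of the sorted X cells or whole animals, or in 4 libraries of the PIWI-1 sorts or the time course. It was called with an adjusted p under 0.05 and a log2 difference of at least 1. X1, X2 and Xins shared 1 fit, whole animals another, the 12 PIWI-1 libraries another, and all 68 regeneration libraries the last, in which each of 16 later times was compared with 0 hr and any change was tested with limma's F test. For each comparison the text names at most 2 rising and 2 falling transcripts, taken from the first 2 by size of change among those called, with a mean of at least 5 FPKM in the higher group and no overlap between the libraries compared.

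Lists were taken from the calls of one experiment and tested in libraries of another: the X1, X2 and Xins lists (called against both other populations for X1 and X2; lower in both X1 and X2 for Xins), irradiation-lowered and irradiation-raised lists, PIWI-1 high, low and negative lists (each called against both other populations for high and low; lower in both high and low for negative), and an early wound list (called higher at 1, 3 or 6 hr). Each test gives the members called higher and lower, the median log2 difference and limma's camera test with a preset correlation of 0.01, adjusted over 67 list tests. Of these, 58 had an adjusted p under 0.05 with camera, 12 with an estimated correlation and 48 with fry, which asks whether members move one way on balance. A list score per library is the median over its members of the log2 value centred per transcript, minus the same median over all transcripts. Scores at each later time were compared with 0 hr by a two-sided exact permutation test of 4 against 4 libraries, adjusted over 128 tests, of which 84 had an adjusted p under 0.05, including those of the early wound list at 1, 3 and 6 hr, the times it was chosen at. The smallest p this exact test can give is 0.0286, and its adjusted value, 0.0435, depends on how many of the tests reach it. All 128 tests use the same 4 libraries at 0 hr, and some lists share members, so the tests are not separate evidence. Overlaps are given beside the number that independent lists of the same sizes would share.

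Libraries that carry the same sort number in the PIWI-1 experiment deviated together from their group means: all 12 same-number pairs had a correlation above 0.1, with a median of 0.67, and all 12 libraries correlated best with a library of their own number. The numbers were therefore taken to pair the PIWI-1 libraries, from the data and not from the labels. The main PIWI-1 fit did not use this pairing, and neither did the lists, the estimated correlations or the simulated data below. The pairing entered only as a block in 1 alternative and in the regrouping of libraries. The fits were tested on simulated data with transcripts changed by a known amount. Noise was drawn independently for each transcript and library, without deviations that libraries share. The changed transcripts lay well above the filter of 1 FPKM and were not among the most abundant. With a change of 1.5 on the log2 scale, 96% of changed transcripts were called for X1 against Xins, 98% for irradiation, 24% for PIWI-1 high against negative and 100% for 6 hr against 0 hr, with at most 6 false calls. With a change of 2.5 the PIWI-1 share was 85%. These shares and false calls hold for that setting and are not estimates for the real libraries or for low transcripts. Alternatives were another pseudocount (0.1), no filter, median-ratio scaling, the replicate number as a block, adjusted p alone, a joint fit of all libraries or a fit of the compared times only, leaving out each library, and, added after seeing the data, limma voom on recovered reads and leaving out whole sorts or times. The library labelled unc_totalRNA entered no test, because the labels give it no group and no replicate.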

Results

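Messenger RNA was sequenced from the planarian *Schmidtea mediterranea*, a flatworm that rebuilds its whole body from dividing stem cells called neoblasts. The 96 libraries fall into 4 experiments and 1 library that the labels place in none. The first experiment holds cells sorted by their DNA dye content into X1 (mostly neoblasts in the later phases of the cell cycle), X2 (a mix of smaller neoblasts and their recent progeny) and Xins (cells that survive irradiation, mostly differentiated), with 3 libraries each. The second holds whole animals, 3 libraries untreated and 3 libraries 24 hours after 10000 rads, a dose that removes neoblasts, with 5 worms per library. The third holds cells sorted by the level of PIWI-1, a protein of neoblasts that persists for a while in their progeny, into high, low and negative populations with 4 libraries each. The fourth follows small fragments cut from one side of the animal over 17 times from 0 hr to 14 days after amputation, with 4 libraries per time.

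Library totals were 33.8 to 40.1 M reads for the sorted X cells and whole animals, 24.2 to 44.3 M for the PIWI-1 sorts and 9.54 to 20.2 M for the regenerating fragments. X1 libraries held 11059 ± 143 (SD, n = 3) transcripts at 1 FPKM or more, X2 libraries 12737 ± 169 and Xins libraries 15285 ± 214. Whole animals held 19610 ± 203 untreated and 19080 ± 135 after irradiation (n = 3). The most abundant transcript in every library took 39.3% ± 2.04 of X1 reads and 12.1% ± 0.643 of untreated reads (SD, n = 3). In the PIWI-1 sorts it took between 16.6% and 61.2%. Single transcripts are given by their identifiers, because the files do not pair these with gene names. All p-values measure the spread between these libraries, and the labels do not say whether the libraries of one group come from separate cultures of animals.

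What sets cycling neoblasts apart from other cells was asked by comparing X1 with Xins. Of 15347 transcripts tested, 1291 were higher and 6117 lower in X1, with at least a 2-fold difference. SMED30030295 stood at 1044 ± 84.2 FPKM in X1 against 49.8 ± 15.5 in Xins (SD, n = 3), a log2 difference of 4.41 with a standard error of 0.20 (limma, adjusted p = 6.99e-09). SMED30002436 was higher by 4.38 ± 0.18 (SE, adjusted p = 5.02e-09 with limma). SMED30014876 went the other way, from 17530 ± 2806 FPKM in Xins to 26.9 ± 11.6 in X1, a log2 difference of -9.37 ± 0.26, and SMED30002134 differed by -9.34 ± 0.28. The median difference over all tested transcripts was -0.68. With median-ratio scaling, which moved that median to -0.00, the split was 3334 higher and 3701 lower.

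X2 cells differed from Xins in fewer transcripts than X1 cells did. Against Xins, 259 transcripts were higher and 2789 lower in X2, among them SMED30023125 (16.5 ± 3.53 FPKM in X2, 0.751 ± 0.511 in Xins, log2 difference 3.34 ± 0.22) and SMED30012180 (9.22 ± 2.06 in X2, 408 ± 112 in Xins, -5.31 ± 0.22). Between X1 and X2, 827 transcripts were higher and 2943 lower in X1. SMED30032688 was higher in X1 than in X2 by 4.54 ± 0.27, and SMED30031990 differed by -8.47 ± 0.20. The median over all transcripts was -0.27 for X2 against Xins and -0.28 for X1 against X2. Median-ratio scaling gave 801 higher and 1733 lower for the first and 1565 higher and 2272 lower for the second.

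Across 15347 transcripts the log2 differences of X1 against Xins and of X2 against Xins correlated with a Pearson r of 0.76 and a Spearman rho of 0.74, where transcripts are not independent replicates. Both comparisons use the same Xins libraries, and unchanged groups simulated against them gave an r of 0.50. The covariance was 1.02 against 0.0157 simulated. Of the calls, 2684 were lower in both X1 and X2, where independent lists of those sizes would share 1112. The simulated groups shared 0 with limma, but this was set in advance, because they held no difference to call. That 0 therefore does not measure what the shared libraries add to the overlap. Part of the excess over 1112 may come from the shared libraries. From these calls 3 lists were drawn for use in other libraries: an X1 list of 709 transcripts higher in X1 than in both other populations, an X2 list of 163 and an Xins list of 2684.

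Irradiated animals were compared with untreated ones to find the transcripts that change after a dose that removes neoblasts. In irradiated worms 341 of 19651 tested transcripts were lower and 33 higher than in untreated worms. SMED30007406 went from 129 ± 3.44 FPKM untreated to 2.07 ± 0.664 irradiated (SD, n = 3), a log2 difference of -5.42 ± 0.13 (limma, adjusted p = 1.21e-06). SMED30030295, named above as higher in X1, went from 44.7 ± 3.59 to 0.324 ± 0.202 FPKM, a difference of -5.12 ± 0.12. SMED30003738 rose from 15.6 ± 3.13 to 108 ± 30.7 FPKM (2.69 ± 0.22), and SMED30005982 rose by 2.45 ± 0.12. Without untreated replicate 1, 2 or 3, the number of calls was 212, 227 or 220 in place of 374. The filter stayed at 1 FPKM in 3 libraries, so it then dropped every transcript under 1 FPKM in all irradiated libraries, such as SMED30030295. These lower counts therefore cannot be read as the weight of 1 library alone.

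Of the irradiation-lowered transcripts with a value in the sorted cells, 197 of 334 belonged to the X1 list, where independent lists would share 12.3. The X1 list, tested in whole-animal libraries that had no part in choosing it, fell after irradiation in 197 of its 521 measured members and rose in 0 (limma), with a median log2 difference of -0.75. The same list changed as a whole by limma's camera test (adjusted p = 1.18e-44) and with an estimated correlation (adjusted p = 0.0382). The X2 list had a median of 0.23 with 2 members higher and 3 lower (camera adjusted p = 3.00e-15, and adjusted p = 0.208 with an estimated correlation). The Xins list had a median of 0.07, with 4 of 2623 members higher and 2 lower (camera adjusted p = 1.20e-06, and adjusted p = 0.129 with an estimated correlation). In the reverse direction, 236 of 334 measured members of the irradiation-lowered list were higher in X1 than in Xins and 24 were lower, with a median of 1.83 (camera adjusted p = 8.13e-45, and adjusted p = 0.129 with an estimated correlation). Of the irradiation-raised list, 14 of 20 measured members were lower in X1 than in Xins and 0 higher (limma), with a median of -1.33, or -0.64 relative to all transcripts (camera adjusted p = 0.0716, so not past the threshold).

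Sorting on PIWI-1 protein asked how expression follows the level of that marker. Between PIWI-1 high and negative cells, 3133 of 15896 transcripts were higher and 4394 lower in the high cells. The larger side turned without PIWI-1 negative replicate 2 (3681 higher, 3306 lower) and without all libraries of the second sort, an alternative added after seeing the data (3314 higher, 3054 lower). SMED30002436, also among the highest in X1, stood at 6.28 ± 4.00 FPKM in negative, 93.9 ± 12.7 in low and 526 ± 97.1 in high cells (SD, n = 4). Its log2 difference between high and negative was 6.33 ± 0.40 (limma, adjusted p = 6.63e-08), and that of SMED30004304 was 5.89 ± 0.42. SMED30025726 stood at 5465 ± 4060 FPKM in negative cells and 8.90 ± 10.6 in high cells (-9.36 ± 0.76), and SMED30011418 differed by -9.02 ± 0.88. The median over all transcripts was -0.17.

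Against negative cells, PIWI-1 low cells had 2193 transcripts higher and 3011 lower. That split became 2724 and 2072 without PIWI-1 negative replicate 2, 2071 and 2020 without replicate 1, and 2409 and 1994 without the second sort. SMED30035904 stood at 3262 ± 875 FPKM in low and 120 ± 88.5 in negative cells (5.10 ± 0.54), SMED30020396 was higher by 5.08 ± 0.51, and SMED30011418 was lower, at 84.4 ± 131 against 3104 ± 2363 (-5.98 ± 0.88). Of the X1 list, 359 of 660 measured members were higher in low than in negative cells and 0 lower (limma), with a median of 1.18 (camera adjusted p = 9.44e-33, and adjusted p = 0.215 with an estimated correlation). Between high and low cells, 380 transcripts were higher and 1144 lower in the high cells, for example SMED30006979 (2.32 ± 0.46) and SMED30006007 (7.99 ± 5.97 against 559 ± 133 FPKM, -6.29 ± 0.66). With the sort number as a block, 577 were higher and 2051 lower in high than in low cells. Pseudocount 0.1 gave 2632 calls there, median-ratio scaling 2496, and leaving out the PIWI-1 high library of the first sort 825.

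Lists chosen in the X cells and in irradiated animals ordered the PIWI-1 populations. In high against negative cells, 592 of 660 measured X1 list members were higher and 0 lower (limma), with a median of 2.39 (camera adjusted p = 3.36e-60, and adjusted p = 0.126 with an estimated correlation). The correlations estimated in the PIWI-1 libraries come from the fit without the sort number, so deviations shared within a sort number count toward them. The Xins list was lower in 1882 of 2373 members, with a median of -2.51 (camera adjusted p = 4.70e-44, and adjusted p = 0.229 with an estimated correlation). Of the irradiation-lowered list, 321 of 337 members were higher, with a median of 3.20 (camera adjusted p = 1.38e-59, and adjusted p = 0.134 with an estimated correlation). The mean score of that list was 1.67 ± 0.158 in high, 0.253 ± 0.148 in low and -1.86 ± 0.150 in negative cells (SD, n = 4, log2 units). In high against low cells the X1 list had a median of 1.19 with 308 members higher (camera adjusted p = 2.17e-85, and adjusted p = 0.0719 with an estimated correlation), and the X2 list had a median of -2.11 with 84 of 156 members lower (camera adjusted p = 2.85e-35, and adjusted p = 0.0394 with an estimated correlation). In low against negative cells the X2 list had a median of -0.20, with 11 members higher and 26 lower (limma's camera, adjusted p = 0.486).

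**Figure D1:**
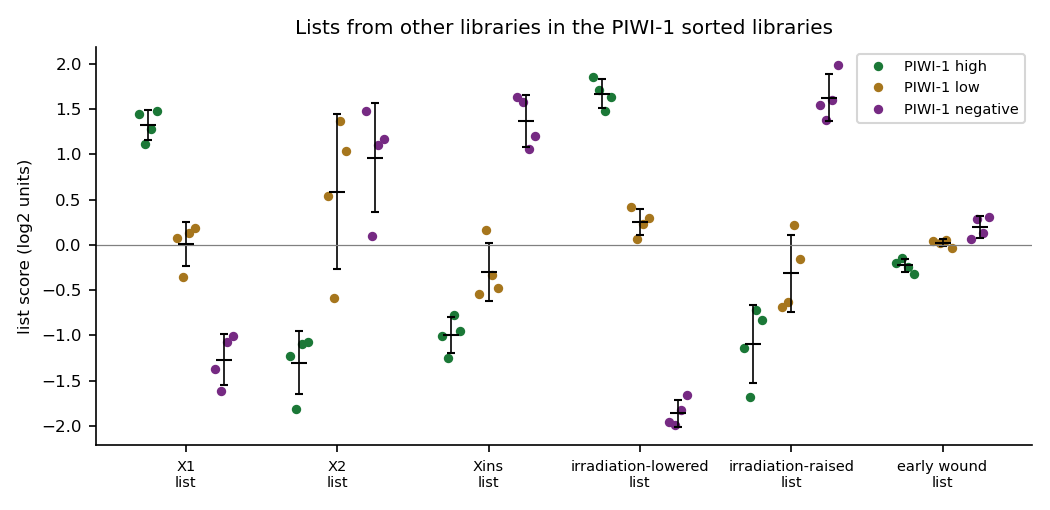
Score of 6 lists in each PIWI-1 sorted library, in log2 units relative to the median of all transcripts, with points for libraries and bars for the mean and SD of 4 libraries. The irradiation-lowered list has a mean of 1.67 in PIWI-1 high, 0.253 in low and -1.86 in negative cells, and the X2 list is spread most widely in low cells.

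Both ways of sorting gave similar differences across transcripts. Over 13846 transcripts the log2 difference of X1 against Xins and that of PIWI-1 high against negative had a Pearson r of 0.76 and a Spearman rho of 0.79 across transcripts, from different libraries. Of 4359 transcripts called in both, 4246 (97.4%) had the same direction. Against the change after irradiation, the X1 to Xins difference had an r of -0.48 and a rho of -0.53 over 14169 transcripts. The X1 list and a PIWI-1 high list of 376 transcripts, higher in high than in both other populations, shared 306 transcripts where independent lists would share 16.3. The Xins list and the PIWI-1 negative list of 2884 shared 1468 against 396, whereas the X1 and PIWI-1 negative lists shared 0 against 110. The X2 list and the PIWI-1 low list of 180 shared 4 against 2.01. In all, 156 transcripts were in the X1, PIWI-1 high and irradiation-lowered lists together.

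The PIWI-1 lists were also tested in the other libraries. The PIWI-1 high list fell in 167 of 275 measured members after irradiation, with a median of -1.17 (camera adjusted p = 6.15e-55, and adjusted p = 0.0237 with an estimated correlation), and 311 of 341 members were higher in X1 than in Xins (median 2.16, camera adjusted p = 1.18e-69, and adjusted p = 0.0394 with an estimated correlation). The PIWI-1 negative list was lower in X1 than in Xins in 2038 of 2313 members, with a median of -1.95, or -1.26 relative to all transcripts (camera adjusted p = 1.69e-25, and adjusted p = 0.144 with an estimated correlation).

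**Figure D2:**
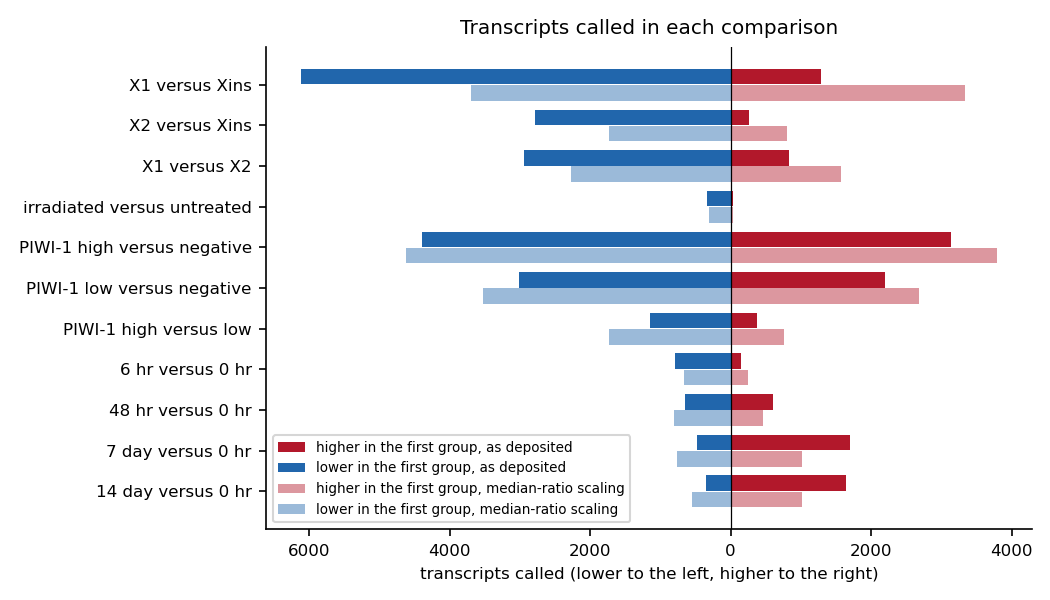
Number of transcripts called higher (right) and lower (left) in the first group of each comparison, for values as deposited (dark bars) and after median-ratio scaling (light bars). In X1 against Xins the split is 1291 higher and 6117 lower as deposited and 3334 and 3701 after scaling, and in PIWI-1 high against low it is 380 and 1144 as deposited and 759 and 1737 after scaling.

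Regeneration was followed to ask when expression changes between amputation and a restored animal. Over the 17 times, 4849 of 24546 tested transcripts passed the limma F test and differed from 0 hr by at least 2-fold at some time. The F test alone passed 22192, so the size of the largest difference did most of the choosing. Neither that size nor its time was itself tested here. At the time of its largest change, 253 transcripts were higher and 746 lower in the window of 1 to 12 hr, 671 higher and 482 lower at 24 to 72 hr, and 2168 higher and 529 lower at 4 to 14 days. Median-ratio scaling gave 297 and 646, 486 and 585, and 1320 and 872 for these windows. Of the 746 lower as deposited, 669 had their largest change at 6 hr, in libraries that held fewer transcripts at 1 FPKM or more. At 9 hr 249 transcripts were called higher than at 0 hr and 59 lower, and at 12 hr 274 and 112. Over all times 3092 were higher and 1757 lower at their largest change, against 5319 and 5694 with pseudocount 0.1, 5377 and 5981 with limma voom and 2103 and 2103 with median-ratio scaling. Without the 3 hr and 6 hr libraries, an alternative added after seeing the data, 4141 transcripts changed.

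The first hours brought a small set of rising transcripts. At 1 hr 28 transcripts were higher than at 0 hr and 2 lower, at 3 hr 93 were higher and 182 lower, and at 6 hr 148 were higher and 797 lower. SMED30031920 rose from 2.54 ± 0.436 FPKM at 0 hr to 81.2 ± 14.2 at 6 hr (SD, n = 4), a log2 difference of 4.53 ± 0.15 (limma, adjusted p = 4.92e-31), and SMED30022580 rose from 0.121 ± 0.0323 to 20.6 ± 3.66 FPKM. Among those that fell at 6 hr, SMED30014570 went from 56.3 ± 28.6 to 6.76 ± 8.87 FPKM (-3.64 ± 1.21, limma adjusted p = 0.0163), and SMED30013245 changed by -3.31 ± 1.08 (limma adjusted p = 0.0150). Both calls were lost without 6 hr replicate 1 (adjusted p = 0.0558 and 0.0706), without 6 hr replicate 6 (0.0789 and 0.0699) and with limma voom (0.0842 and 0.0672).

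All 4 libraries at 6 hr held fewer transcripts at 1 FPKM or more, 16136 ± 163 against 18832 ± 466 at 0 hr (SD, n = 4), and so did 3 of 4 at 3 hr. The median of all transcripts at 6 hr was -0.15, and with median-ratio scaling the 6 hr split was 251 higher and 660 lower. With pseudocount 0.1, which gives low transcripts more weight, 253 were higher and 4087 lower at 6 hr. Without 3 hr replicate 5, which held 18741 such transcripts, the 3 hr calls were 90 higher and 425 lower.

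A list of 186 early wound transcripts, higher at 1, 3 or 6 hr, was followed to the end of the course. It was chosen with the same 0 hr libraries that later times are compared with, so its later values are not independent of that choice, and its score of 1.39 above 0 hr at 6 hr follows from the choice itself. The score stood at 0.51 above 0 hr at 48 hr (4 of 4 libraries above every 0 hr library, exact permutation test, two-sided p = 0.0286, adjusted p = 0.0435 over 128 list and time tests) and at -0.12 at 14 days (exact permutation adjusted p = 0.109). In other experiments, 95 of its 154 measured members were lower in X1 than in Xins and 11 higher, with a median of -1.26, or -0.57 relative to all transcripts (camera adjusted p = 0.0106, and adjusted p = 0.343 with an estimated correlation). After irradiation 1 of 162 members was higher and 4 were lower, with a median of 0.00 (limma's camera, adjusted p = 0.294).

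**Figure D3:**
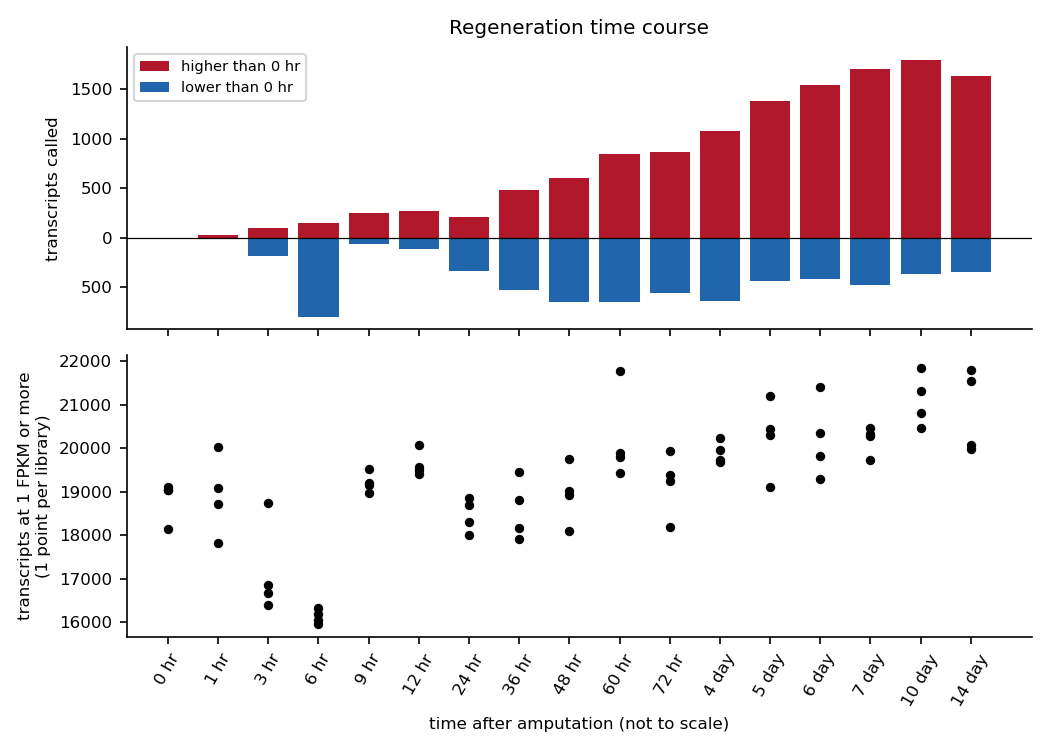
Upper panel: transcripts called higher or lower than 0 hr at each of 16 later times. Lower panel: number of transcripts at 1 FPKM or more, 1 point per library; all 4 libraries at 6 hr lie between 15956 and 16329, below every library at 0 hr.

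The middle of the course is described at 48 hr, when 598 transcripts were higher and 645 lower than at 0 hr, a split whose larger side turned with pseudocount 0.1 (1223 higher, 1041 lower), with limma voom (1260 and 1065), with adjusted p alone (6434 and 3099) and without 48 hr replicate 4 (621 and 619) or 0 hr replicate 1 (649 and 634). SMED30022734 went from 7.78 ± 2.34 to 1214 ± 742 FPKM (6.61 ± 1.23, limma adjusted p = 1.23e-05), while SMED30033452 went from 345 ± 160 to 5.43 ± 8.99 FPKM (-6.55 ± 0.90) and SMED30034731 from 224 ± 108 to 2.76 ± 4.80. Of the X1 list, 92 of 655 measured members were higher and 4 lower at 48 hr, with a median of 0.48 (camera adjusted p = 1.33e-16, and adjusted p = 0.0382 with an estimated correlation). The irradiation-lowered list had a median of 0.73 with 89 of 341 members higher (camera adjusted p = 3.63e-35, and adjusted p = 0.0382 with an estimated correlation). Median-ratio scaling gave 457 higher and 804 lower at 48 hr.

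The X1 list score stood above 0 hr at 3, 6 and 9 hr (0.13, 0.14 and 0.09) and from 24 hr to 10 days (exact permutation adjusted p = 0.0435 at each), and the PIWI-1 high and irradiation-lowered lists did so from 3 hr to 10 days. The 3 hr and 6 hr values come from libraries of which 7 of 8 held fewer transcripts at 1 FPKM or more, and the X1 list members' median log2 difference at 6 hr was -0.05 against -0.15 for all transcripts. With median-ratio scaling the PIWI-1 high list lost its call at 3 hr (exact permutation adjusted p = 0.0762). The highest point of the 3 lists was at 72 hr. Relative to 0 hr the X1 list stood at 0.49 at 72 hr and 0.07 at 14 days, the PIWI-1 high list at 0.60 and 0.09, and the irradiation-lowered list at 0.68 and 0.12. At 72 hr all 4 libraries lay above every 0 hr library for each of these lists (exact permutation test, adjusted p = 0.0435, where 0.0286 is the smallest p that 4 against 4 libraries allow). At 14 days the adjusted p was 0.169, 0.169 and 0.109 by the same exact test. Each list differed between 48 hr and 14 days, by 0.34 for the X1 list, 0.44 for the PIWI-1 high list and 0.51 for the irradiation-lowered list (exact permutation p = 0.0286).

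The Xins list score stood above 0 hr at 6 hr and again from 4 days on, where the 4 day value of 0.08 (exact permutation adjusted p = 0.0435) lost its call with pseudocount 0.1 (adjusted p = 0.0762) and with median-ratio scaling (adjusted p = 0.109). At 6 hr its score was 0.16 above 0 hr, with 4 of 4 libraries above every 0 hr library (exact permutation adjusted p = 0.0435), in the libraries that held fewer transcripts at 1 FPKM or more, but the members' median log2 difference was -0.05 against -0.15 for all transcripts. At 9 hr the score was -0.03 (exact permutation adjusted p = 0.257). From 12 hr to 60 hr it lay between -0.04 and -0.09, short of the threshold at each time (exact permutation adjusted p from 0.0778 to 0.229). It was 0.00 above 0 hr at 72 hr (exact permutation adjusted p = 0.943), 0.25 at 7 days and 0.30 at 14 days, with 4 of 4 libraries above every 0 hr library at the last 2 of these (exact permutation adjusted p = 0.0435). At 14 days 704 of 2664 measured members were higher and 89 lower, with a median of 0.54 (camera adjusted p = 2.76e-07, and adjusted p = 0.126 with an estimated correlation). The PIWI-1 negative list score stood at 0.11 at 6 hr (exact permutation adjusted p = 0.0435, members' median log2 difference -0.08), -0.16 at 48 hr and 0.26 at 14 days.

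X2 list transcripts fell furthest. At 48 hr 114 of 161 measured members were lower and 12 higher, with a median of -1.93 relative to all transcripts (camera adjusted p = 1.34e-19, and adjusted p = 0.0527 with an estimated correlation). At 7 days 80 were lower and 9 higher (median -1.71 relative to all transcripts, camera adjusted p = 1.15e-20, and adjusted p = 0.0466 with an estimated correlation). At 14 days 43 were lower and 21 higher (median -0.57 relative to all transcripts, camera adjusted p = 5.38e-14, and adjusted p = 0.126 with an estimated correlation). The members' own median log2 difference at 14 days was -0.32 (quartiles -1.63 and 0.63), nearer to 0 than the list score. The list score was lowest at 4 days, at -3.39 relative to 0 hr, and stood at -1.29 at 14 days, with 4 of 4 libraries below every 0 hr library (exact permutation adjusted p = 0.0435). The irradiation-raised list fell too, to -1.28 at 14 days, where 14 of 32 members were lower and 1 higher (camera adjusted p = 9.22e-16, and adjusted p = 0.0361 with an estimated correlation).

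**Figure D4:**
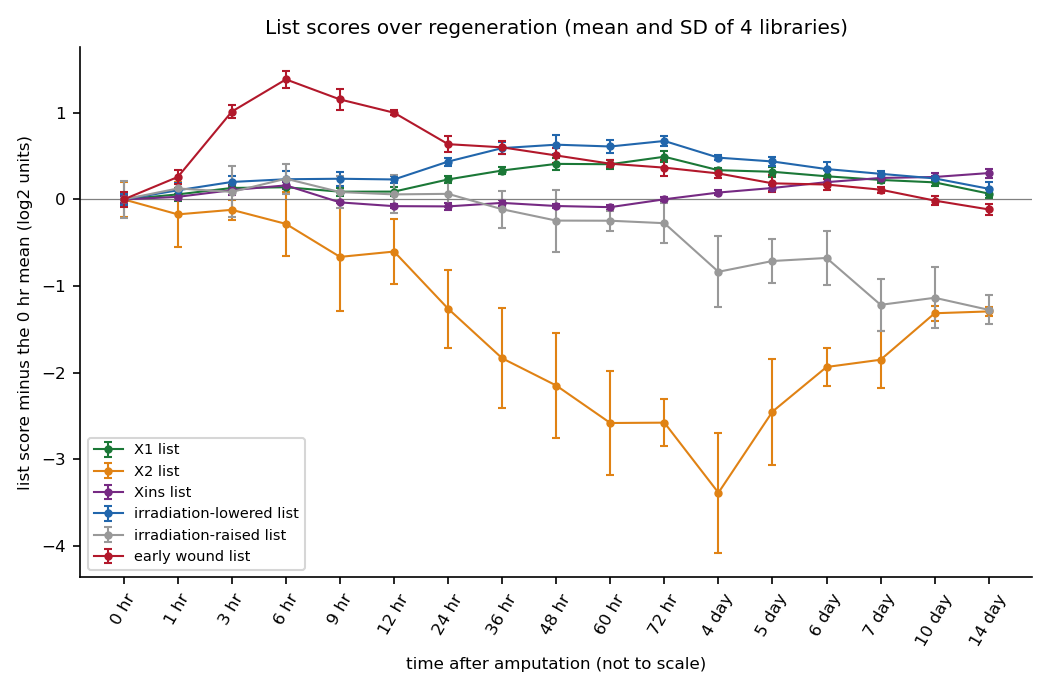
Mean list score relative to 0 hr, in log2 units, at 17 times after amputation, with bars for the SD of 4 libraries. The early wound list, chosen as higher at 1, 3 or 6 hr, stands at 1.39 at 6 hr, the X1 and irradiation-lowered lists are highest at 72 hr (0.49 and 0.68), and the X2 list is lowest at 4 days (-3.39).

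Late regeneration was marked by more rising than falling transcripts. At 7 days 1706 transcripts were higher and 481 lower than at 0 hr, and at 14 days 1636 and 346. The median of all transcripts was 0.21 at 7 days and 0.25 at 14 days, and median-ratio scaling gave 1015 higher and 760 lower at 7 days and 1022 and 555 at 14 days. Libraries held 19721 to 20462 transcripts at 1 FPKM or more at 7 days and 19990 to 21811 at 14 days, against 18135 to 19121 at 0 hr. As at 6 hr, a library batch and the time cannot be told apart there. SMED30032293 was listed at 0 in all 4 libraries at 0 hr and stood at 115 FPKM at 7 days, from 42.5 to 183 in its 4 libraries. SMED30023924 stood at 0.0621 ± 0.0724 FPKM at 0 hr, 97.9 ± 53.6 at 7 days and 265 ± 62.8 at 14 days (SD, n = 4). SMED30004108 fell from 129 ± 24.3 to 0.639 ± 0.523 FPKM at 7 days (-6.34 ± 0.72) and SMED30027739 from 93.4 ± 25.9 to 0.518 ± 0.218 (-5.93 ± 0.47). SMED30032042 went from 0.0385 ± 0.0771 FPKM at 0 hr to 346 ± 50.1 at 14 days. SMED30002911 fell from 2445 ± 232 to 2.24 ± 0.479 FPKM at 14 days (-9.57 ± 0.51, limma adjusted p = 4.88e-23) and SMED30007501 from 4087 ± 807 to 4.75 ± 0.893 (-9.46 ± 0.52).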

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

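In the weighing below, the tests on abundant transcripts and on a library batch for the 6 hr pattern were chosen only after the result was seen. Of 266 groups of 4 libraries checked for one library far from the other 3, 23 had one, where chance gives about 1 in 20, or 13.3. These were 7 of 60 groups of library measures, 8 of 154 of list scores and 8 of 52 of named transcripts.

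The library measures with one library apart were as follows. PIWI-1 negative replicate 1 had 24.2 M reads against 31.0 to 32.4 M in the others, and replicate 4 gave 61.2% of its reads to the most abundant transcript against 26.2% to 31.9%. In the time course, 0 hr replicate 3 had 18135 transcripts at 1 FPKM or more against 19035 to 19121. The most abundant transcript took 12.8% of reads in 1 hr replicate 1 (others up to 11.5%), 13.5% in 3 hr replicate 6 (others up to 12.03%) and 11.6% in 4 day replicate 5 (others from 14.1%). At 60 hr replicate 6 had 14.2 M reads against 16.5 to 16.8 M.

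Among list scores, the X2 list stood at -1.47 in 72 hr replicate 5 against -0.98 to -0.92 in the others. The Xins list stood at -0.119 in 9 hr replicate 5 (others from -0.0991) and at -0.182 in 48 hr replicate 5 (others from -0.134). For the irradiation-lowered list, 6 hr replicate 1 stood at 0.0294 (others up to -0.142) and 9 hr replicate 5 at 0.0173 (others up to -0.132). The PIWI-1 negative list stood at -0.116 in 9 hr replicate 5, and the early wound list at 0.562 in 12 hr replicate 6 and at 0.000936 in 36 hr replicate 6. Of these 8, 9 hr replicate 5 gave 3.

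Among named transcripts, SMED30025726 stood at 24.7 FPKM in PIWI-1 high replicate 2 (others up to 5.41) and at 355 in PIWI-1 low replicate 2 (others up to 49.5). SMED30011418 stood at 16.5 and 281 FPKM in the same libraries, against others up to 2.90 and 21.8. In 48 hr replicate 5, SMED30033452 stood at 18.9 FPKM (others up to 1.44) and SMED30034731 at 9.94 (others up to 0.698). SMED30032042 was at 0.154 FPKM in 0 hr replicate 3 and listed at 0 in the others, and SMED30002911 was at 2.95 FPKM in 14 day replicate 6 (others up to 2.10).

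All 8 lists followed over regeneration differed between 48 hr and 14 days (exact permutation test of 4 against 4 libraries, p = 0.0286, the smallest it can give; adjusted p = 0.0286). The difference in score, 48 hr minus 14 days, was 0.34 for the X1 list, 0.51 for the irradiation-lowered list, 0.44 for the PIWI-1 high list, 0.62 for the early wound list and 1.03 for the irradiation-raised list. It was -0.86 for the X2 list, -0.38 for the Xins list and -0.43 for the PIWI-1 negative list. The unc_totalRNA library, which no comparison uses, had 27872 transcripts with more than 3 reads.

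All 4 libraries at 6 hr held fewer transcripts at 1 FPKM or more than any at 0 hr, at most 16329. The tables argue against depth: 0 hr libraries thinned to the smallest 6 hr depth held 18852 on average and at least 18171. A larger share of reads in a few transcripts would lower all others alike, but transcripts at 10 FPKM or more at 0 hr had a median log2 ratio of -0.053 (quartiles -0.21 and 0.11) against -1.02 (-1.72 and -0.36) for those between 0.2 and 2 FPKM. A library batch stays open: 3 of the 4 libraries at 3 hr also lay below every 0 hr library while the fourth did not, a division within 1 time that a batch may give, and because all 4 libraries at 6 hr are low, batch and time cannot be told apart there. A response to the wound that lowers rare transcripts stays open as well and was not tested apart from this.

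PIWI-1 libraries of the same sort number deviated together, with a median correlation of 0.67 over 12 pairs. Pairs of different numbers had a median of -0.19 and reached 0.60. In each population the second sort held the most transcripts at 1 FPKM or more. It held 14747 in high, 16804 in low and 19473 in negative cells, against at most 11667, 12971 and 15719 in the other sorts. How much of the shared deviation rests on that sort was not tested. Abundant transcripts argue for little of the shared deviation, since the median was 0.62 and the lowest pair 0.17 after the 10 most abundant transcripts were removed and the rest rescaled. Depth argues for none of it at the smallest common depth, where the median was 0.664 and the lowest pair 0.123. The day of the sort, the library batch and the animals used for each sort stay open, since the labels give none of them.

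Most transcripts called between X1 and Xins were lower in X1, with a median over all transcripts of -0.68. It was -0.54 without the 10 most abundant transcripts, which took 42.8% of X1 reads and 31.9% of Xins reads, with 2034 calls higher and 6252 lower, so these can be only part of the cause. At equal depth it was -0.685, so depth does not account for all of it. Of 5 length classes the shortest, the least affected, had -0.32 and the longest, the most affected, -0.95, so the difference varied with length. Length does not account for all of it either, as every class had a median under 0. Median-ratio scaling centres the median by construction and made 3334 calls higher and 3701 lower. The filter also admits transcripts that reach 1 FPKM in the 3 Xins libraries alone. Xins libraries held 15285 transcripts at 1 FPKM or more on average, against 11059 in X1. What the filter adds to the lower side was not weighed here. Whether X1 cells hold less RNA of many kinds, or more of the rest, stays open too, as no library holds a reference amount of RNA.

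Regrouping the same libraries set each count beside those of other groupings. With 3 against 3 libraries the 10 splits are too few for a share under 0.05. There the real counts were 7408, 3048, 3770 and 374 for X1 against Xins, X2 against Xins, X1 against X2 and irradiation, and the highest other split gave 0 with limma in each, so 1 split of 10, the real one, gave as many. For the 4 times tested this way, 1 of 35 splits of 4 against 4, the real one, gave as many, a share under 0.05 and the smallest possible. The highest other was 94 of 945 at 6 hr, 487 of 1243 at 48 hr, 468 of 2187 at 7 days and 383 of 1982 at 14 days. Every other split mixes the groups compared, so a large difference of any cause, a batch included, puts the real split first. The share therefore speaks only against a random grouping of these libraries, at that threshold, and not for the number called. For PIWI-1, where the numbers pair the libraries, 8 splits part every pair, too few for a share under 0.05. The real counts were 7527 for high against negative, 5204 for low against negative and 1524 for high against low, and the highest other of these 8 gave 0 with limma in each. Among the splits of all 35 that keep a pair together the highest was 0 for high against negative, 1 for high against low and 4522 for low against negative, from exchanging the low library of the second sort with the negative library of the third. Of 100 splits for any change, the highest other gave 566 against 4849.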

How the results depend on the processing

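Of the alternatives, limma voom on recovered reads, leaving out whole PIWI-1 sorts, and leaving out 3 hr and 6 hr were chosen only after the result was seen. Counts of calls stayed within 1.5 times in 203 of the alternatives run on the 12 counts that answer a comparison and moved in 32. Many of these alternatives left out 1 library, 68 of them from the test of any change, where the count ran from 4771 to 5132. Leaving out 1 library moved only counts for irradiation and for PIWI-1 high against low. Most moves therefore came from the other alternatives. Apart from the following, the cause of each move was not tested. Dropping the minimum difference lets smaller differences in by construction. Leaving out an untreated library drops transcripts under 1 FPKM in all irradiated libraries from the fit. With adjusted p alone the calls were 12178 for X1 against Xins, 8591 for X2 against Xins, 9158 for X1 against X2, 6370 for irradiation, 7941, 9533, 12123 and 11697 for 6 hr, 48 hr, 7 days and 14 days, and 22192 for any change. Pseudocount 0.1 gave 6019 for X1 against X2, 581 for irradiation, 2632 for PIWI-1 high against low, 4340, 2264, 3770 and 3559 for the 4 times and 11013 for any change. With limma voom there were 4600 for X2 against Xins, 6065 for X1 against X2, 620 for irradiation, 2712 for PIWI-1 high against low, 4198, 2325, 3973 and 3827 for the 4 times and 11358 for any change. Median-ratio scaling gave 2496 for PIWI-1 high against low. Scaling also turned the larger side of the splits at 60 hr, 72 hr and 4 days, and adjusted p alone that at 24 hr and 36 hr.

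The sort number as a block gave 2628 calls for PIWI-1 high against low in place of 1524, all 1524 of them kept. High against negative had 8247 calls with it and low against negative 6153, within 1.5 times of the values above. In the other experiments the numbers do not pair the libraries: same-number correlations ran from -0.06 to 0.34 in the X cells, where 5 of 9 libraries correlated best with their own number, from -0.55 to 0.41 in whole animals (1 of 6), and had a median of 0.01 in the time course (11 of 68). There the replicate block gave 7408, 3060, 3772 and 374 calls for X1 against Xins, X2 against Xins, X1 against X2 and irradiation, 1044, 1255, 2180 and 1972 for the 4 times and 4981 for any change.

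Leaving out 1 library at a time gave 6096 to 7351 calls for X1 against Xins, 2085 to 3094 for X2 against Xins, 3657 to 3874 for X1 against X2, 212 to 369 for irradiation (212, 227 and 220 without untreated replicate 1, 2 and 3), 6358 to 7309 for PIWI-1 high against negative, 4000 to 5050 for low against negative and 825 to 1392 for high against low (825 without the high library of the first sort). For 6 hr, 48 hr, 7 days and 14 days it gave 840 to 1180, 1118 to 1474, 2075 to 2312 and 1929 to 2049, and for any change 4771 to 5132. The number of libraries that the filter asks for was not lowered in these fits.

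With an estimated correlation the median of the X1 list in PIWI-1 high against negative, 2.56 relative to all transcripts, had an adjusted p of 0.126 with limma's camera, and that of the irradiation-lowered list in X1 against Xins, 2.51, one of 0.129. For the X1 list the estimated correlation was 0.51 in the PIWI-1 libraries and 0.057 in whole animals. In the PIWI-1 libraries it came from the fit without the sort number, so deviations shared within a sort number count toward it. No estimate with the sort number as a block was made. Over all list tests the estimated correlation kept 12 of 58 calls and ended 46, while pseudocount, scaling and block together ended 1 and added 4. Of the values of named transcripts 586 kept their call and 7 lost it: SMED30014570 and SMED30013245 at 6 hr as given above, and SMED30035874 at 48 hr with limma voom (log2 difference 6.49, adjusted p = 0.157, against 6.20 and 0.000125). The list scores over time kept their side of the threshold in 245 alternatives, passed it in 8 and missed it in 3. Correlations across transcripts moved to 0.81, -0.44 and 0.77 with pseudocount 0.1. Gene lists fixed by name were not run for want of names.

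On simulated data the fit of PIWI-1 high against negative missed most changes of 1.5, so transcripts not called there are not shown to be unchanged. The other PIWI-1 comparisons were not simulated.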

Other observations

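The test of the hypothesis below was written before its result was seen, but the margin by which its bound had to be met was chosen only after the result was seen. The irradiation-raised list had a value in the PIWI-1 sorts for 19 of its 33 members. Of these, 15 were lower and 1 higher in PIWI-1 high than in negative cells, with a median of -3.02 (limma's camera, adjusted p = 1.83e-07, and adjusted p = 0.213 with an estimated correlation), and 15 were lower in low than in negative cells. The list score was 1.63 ± 0.257 in negative, -0.314 ± 0.428 in low and -1.09 ± 0.428 in high cells (SD, n = 4). Only 1 of its members was also in the early wound list, where independent lists would share 0.264, and its score at 6 hr was 0.24 above 0 hr (exact permutation adjusted p = 0.198). That member, SMED30003738, rose both after irradiation and at 6 hr.

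The X2 list had 2 members higher and 3 lower of 153 after irradiation. It shared 3 transcripts with the irradiation-lowered list where independent lists would share 3.61, and the Xins list shared 2 where they would share 61.8. The X2 list had 97 of 156 members lower in PIWI-1 high than in negative cells and 6 higher, with a median of -1.88 (limma's camera, adjusted p = 9.88e-11, and adjusted p = 0.215 with an estimated correlation). Its score was spread most in PIWI-1 low cells, from -0.587 to 1.37.

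A hypothesis for the fall of the X2 list during regeneration is that its falling members may be transcripts of PIWI-1 low cells, which would be higher in low than in negative cells. Over the 113 members that fell at 48 hr and had a value, the median difference of low minus negative was -0.21 (quartiles -1.10 and 0.88). Of these members 2 were called higher and 20 lower in low cells (limma), where 2193 of all 15896 transcripts were called higher and 3011 lower. The bound set against the hypothesis beforehand, an upper quartile under 1, was met, and the lower quartile was not above 0 as the hypothesis needs. By the bound set beforehand, these values argue against the hypothesis for the 113 members as a set. The margin chosen afterwards was not met, because the upper quartile lies under that bound by less than the spread of the members. Members lie on both sides of 0, so the hypothesis stays open for single members. The same members had a median of -2.12 in high minus negative cells, and the X2 list members that did not fall had a median of -0.07 in low minus negative cells.

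The unc_totalRNA library, deposited with the PIWI-1 sorts, had 33.9 M reads and 19806 transcripts at 1 FPKM or more, against 12897 to 19473 in PIWI-1 negative libraries and 19446 to 19837 in untreated whole animals. Its most abundant transcript took 8.81% of reads. SMED30002436 stood at 45.5 FPKM in it and at 39.2 ± 3.49 in untreated animals (SD, n = 3). SMED30030295 stood at 51.8 FPKM in it and at 44.7 ± 3.59 in untreated animals.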
